A study of Mus musculus with 3 samples.

How the data were processed

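Single-cell RNA libraries of mouse non-small cell lung cancer, 1 per group, were made with 10x Genomics 3′ chemistry and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The labels name the groups PBS, PD-L1 and AI-Exo and no sort, and whether cells were enriched for immune cells is not given in the sources used here. The values are counts of UMIs per gene and barcode, whole numbers that were not normalized, as deposited by the authors. The matrices were made with Cell Ranger 7.1.0 per the file headers, whereas the submitters' processing notes list 3.0.2. The genome build, the annotation and whether intronic reads were counted are not given in the sources used here. Each matrix held 32285 genes and all barcodes, 840360 in PBS, 794333 in PD-L1 and 858023 in AI-Exo. Where 2 or more identifiers shared a symbol (40 symbols), the first was used. Near-identical gene copies such as Hspa1a with Hspa1b and Ifit3 with Ifit3b share sequence, so their separate values are uncertain.

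Cells were separated from empty droplets here. Barcodes with at least 500 UMIs numbered 9509, 9894 and 10580 in PBS, PD-L1 and AI-Exo. Of these, 62, 102 and 55 had fewer than 200 genes, and 88, 95 and 68 had over 20% mitochondrial UMIs. Barcodes were compared with free RNA, estimated from barcodes of at most 100 UMIs, by a Dirichlet-multinomial Monte Carlo test with 1000 draws and a false discovery rate of 0.01, and barcodes of 5000 UMIs or more were kept. A barcode counted as a cell if any of 3 statistics set it apart, which left out 361, 305 and 357 barcodes. The likelihood statistic alone would have left out 1138, 1063 and 1217. Scrublet in scanpy scored doublets. Its automatic thresholds of 0.619, 0.618 and 0.630 marked 0 cells in each library, so a score of 0.15 was used and removed 472, 518 and 598 cells (5.25%, 5.52% and 5.92%). That left 8526, 8874 and 9502 cells with 57350045, 55035814 and 63449456 UMIs.

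Counts were scaled to the cell total and log-transformed, 2000 variable genes and 30 principal components were taken, and 15 neighbours and Leiden clustering at resolution 1 gave 34 clusters, with no integration of the libraries. Clusters were named from fixed markers, each at 20 CPM or more and at least 2-fold above the other cells. A cluster with fewer than 3 such markers, with leading markers of a second type or with a median doublet score of 0.1 or more stayed unnamed. Immature T-lineage clusters needed 3 T cell markers and 2 genes of the precursor list. The T cells were clustered again into 19 sub-clusters. Those with CD8 or CD4 markers formed the CD8 and CD4 T classes, unless markers of another type outnumbered their own among the leading genes. That rule left T10 (Cd8b1 at 501.6 CPM) out of the CD8 class, and T5 and T16 (Cd4 at 193.0 and 133.1 CPM) out of the CD4 class. T13, with CD4 and regulatory T markers, was kept apart. Sub-clusters that stayed unnamed held 31.9%, 25.7% and 24.7% of the T cells in PBS, PD-L1 and AI-Exo. CPM was the sum of a gene's UMIs in a class and library per 1000000 UMIs of that sum. Ratios are log2 of CPM plus 10 in 1 library over CPM plus 10 in the other, which pulls the ratios of low genes toward 0.

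With 1 library per group no test was made. Sums carry exact Poisson intervals, shares exact Clopper-Pearson intervals and list medians intervals from 200 Poisson redraws, all at 95% and all covering counting error only. Genes were called higher or lower by size at a ratio of 1.5. A list was described by the members with a mean of at least 10 CPM, and its median was placed among 10000 random lists matched on expression, as a description of these libraries. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. The genes named were the 3 highest and 3 lowest in each of the 4 largest classes among those at 100 CPM or more in the higher library, with at least 50 UMIs. Mitochondrial, ribosomal, antigen receptor segment, haemoglobin, sex-linked, predicted and clone-named genes were left out. The highest and lowest list members at 50 CPM or more, the 2 members with most UMIs and a fixed set of single genes were also named. Counts were also simulated from the profile of each class pooled over the libraries, with counting error only and no variation between libraries. Among genes at 100 CPM or more, 200 were changed, of 1564 in B cells, 1579 in T cells, 1331 in neutrophils and 1552 in monocytes. There 4-fold changes passed the size in 100.0% and unchanged genes in 0%, which says nothing of lower genes or of differences between libraries. For 2-fold changes the share was 99.0% in neutrophils for AI-Exo against PBS and 100.0% in the other comparisons.

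The groups, the filters on UMIs, genes and mitochondrial share, the markers, the 24 gene lists, the naming rule and most alternatives were fixed before the data were examined. Choices made after seeing the data were the use of any of 3 statistics against free RNA, the doublet score, leaving clusters with a median doublet score of 0.1 or more unnamed, setting aside 6 cells with 10% or more haemoglobin UMIs, and the immature T-lineage markers. So were the 5-fold rule for CD8 and CD4, the class in which each list is described, the order of results, and 5 alternatives (the likelihood statistic alone, the immature T-lineage class left out, cluster 17 counted among T cells, the largest cluster alone, single clusters of resolution 2). Other alternatives changed the UMI minimum, the mitochondrial limit, doublet removal, the principal components, the resolution, free RNA subtraction, the pseudocount, the expression minimum, the scaling and the weight of cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, numba 0.67.0 and matplotlib 3.10.9 were used.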

Results

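Droplet single-cell RNA sequencing was used to count transcripts in cells from mouse non-small cell lung cancer. The 3 libraries carried the group labels PBS, PD-L1 and AI-Exo, with 1 library per group, and the labels used here do not spell the names out. The matrices held 68386729 UMIs (unique molecular identifiers, each counting 1 captured transcript) for PBS, 65997942 for PD-L1 and 76512500 for AI-Exo. After filtering, 8526, 8874 and 9502 cells remained, with medians of 4330.0, 3894.0 and 4361.5 UMIs and of 1652.5, 1528.5 and 1665.0 genes per cell. The series asks how immune cells in the tumour differ after drug treatment, and its title names exosomes that inhibit autophagy and immune tolerance. Because each group was a single library, no difference has a replicate check and none was tested. Brackets give 95% intervals that cover counting error only, and "higher" or "lower" describes the size of a ratio between these libraries.

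The cells formed 34 clusters, and 28 of them could be named from markers. B cell-like cells (Cd79a, Ms4a1), T cell-like cells (Cd3e, Trac), neutrophil-like cells (S100a8, Csf3r) and monocyte-like cells (Ly6c2, Vcan) made up the 4 largest classes. Macrophage-like, alveolar macrophage-like, NK-like, 3 dendritic cell-like classes, γδ T-like, plasma cell-like, ILC2-like and endothelial-like cells made up the smaller ones. Clusters 11, 14, 17 and 24 expressed T cell genes and were called immature T-lineage-like from a list of T cell precursor genes chosen after the clusters were seen. Clusters 11 and 14 expressed Rag1, Dntt and Arpp21 of that list, and cluster 24 expressed Dntt and Arpp21. Cluster 17, with 148 PBS, 206 PD-L1 and 4 AI-Exo cells, expressed only Ccr9 and Sox4 of that list, so its name is less firm. The immature T-lineage class held 988 PBS cells (11.6% [10.9 to 12.3]), 994 PD-L1 cells (11.2% [10.6 to 11.9]) and 4 AI-Exo cells (0.0421% [0.0115 to 0.108]), all 4 of them in cluster 17. With cluster 17 counted among T cells the PBS and PD-L1 shares were 9.85% and 8.88%. The unnamed clusters held 1.88%, 3.02% and 2.61% of the cells in PBS, PD-L1 and AI-Exo. The unnamed cluster 27, led by Rhox5, Hmga2 and Krt8, had a median of 52192.0 UMIs per cell and held 0.528%, 0.259% and 0.526%. The unnamed cluster 26, with markers of both B and T cells, held 0.457%, 0.980% and 0.0316%. The unnamed cluster 19, with markers of neutrophils and monocytes, held 0.622%, 1.05% and 1.26%. The other unnamed clusters were 31 with haemoglobin and neutrophil genes (0.0704%, 0.372% and 0.389%), 32 led by Scgb1a1 and Sftpc (0.176%, 0.27% and 0.295%) and 33 led by Il6, Gata2 and Mcpt8 (0.0235%, 0.0902% and 0.105%). Cluster 33, of 20 cells, had 8 of 8 mast cell or basophil markers and stayed unnamed for a median doublet score of 0.126. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

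**Figure D1:**
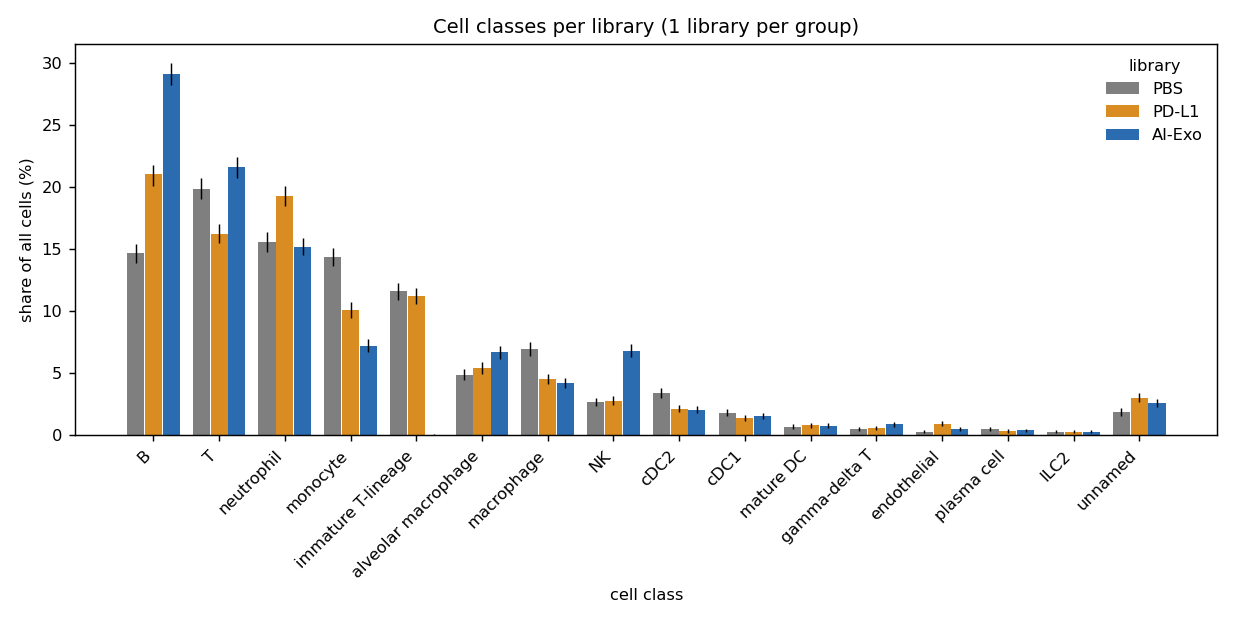
Share of all cells (percent, vertical axis) in each cell class (horizontal axis) for the PBS, PD-L1 and AI-Exo libraries, with bars for the share and error bars for the exact 95% binomial interval. B cell-like cells were at 14.7%, 21% and 29.1%, NK-like cells at 2.67%, 2.79% and 6.81%, and immature T-lineage-like cells at 11.6%, 11.2% and 0.0421%.

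The first comparison set the PD-L1 library against the PBS library. Genes of the type I interferon response were higher in the PD-L1 library, most of all in neutrophil-like and monocyte-like cells. In neutrophils, 18 of the 18 measured members were at least 1.5 times higher, with a median log2 ratio of 2.06 [1.96 to 2.19]. In monocytes, 19 of 19 were higher, with a median of 1.45 [1.37 to 1.52]. Both medians lay at percentile 100 of 10000 random lists of the same size matched on mean expression, which describes these libraries and is no test. At a finer clustering (resolution 2) the libraries lay in different neutrophil clusters. Cluster 16, led by Slfn4 and with the interferon-induced Rsad2 and Ifit3 among its top genes, held 27 PBS and 677 PD-L1 neutrophils, and cluster 6 held 647 and 151. The median was 0.27 [0.06 to 0.51] within cluster 16, 0.85 [0.62 to 1.02] within cluster 7 (434 and 199 cells) and between 1.55 and 2.18 within clusters 1, 6 and 33. In monocytes cluster 14 held 788 PBS and 74 PD-L1 cells and cluster 5 held 221 and 572, and the median was 1.24 within cluster 5, 1.56 within cluster 14 and between these within cluster 25 (152 and 130 cells). Cluster 29, which is unnamed at that resolution and led by Ctsg, Mpo and Prtn3, held 39 PBS, 109 PD-L1 and 174 AI-Exo cells of the monocyte class, and its median was 1.31 [0.62 to 1.74]. Those leading genes are of all its cells together. Its PBS and PD-L1 cells had no Ctsg UMI, and its PD-L1 cells had no Prtn3 UMI. B cell-like cells made up 21% [20.1 to 21.8] of the PD-L1 cells and 14.7% [13.9 to 15.4] of the PBS cells, a ratio of 1.43 [1.33 to 1.54].

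Among single interferon-induced genes, Ifit3 (ENSMUSG00000074896) reached 669.2 [647.8 to 691.1] UMIs per 1000000 UMIs of the class (CPM) in PD-L1 neutrophils and 36.1 [30.3 to 42.8] in PBS neutrophils, a log2 ratio of 3.88. Its near-identical copy Ifit3b (ENSMUSG00000062488) had a log2 ratio of 3.22, and how UMIs were split between the 2 copies is uncertain. Ifi27l2a (ENSMUSG00000079017), also interferon-induced, was at 3062.2 against 405.4 CPM, a log2 ratio of 2.89. The member of the list nearest to 0 in neutrophils was Oasl2, at 1.28, and Isg15, a ubiquitin-like modifier, was at 2.25. In monocytes Ifit2 (ENSMUSG00000045932) was at 512.0 [490.1 to 534.6] CPM in PD-L1 and 52.7 [48.1 to 57.7] in PBS, a log2 ratio of 3.06, followed by Slfn4 (ENSMUSG00000000204) at 2.80 and Ifit1 (ENSMUSG00000034459) at 2.75. The median of the list was 0.92 [0.81 to 1.0] in macrophages (14 of 18 members higher), 0.83 [0.72 to 0.96] in B cells (12 of 16) and 0.61 [0.42 to 0.69] in cDC2-like dendritic cells (10 of 19). It was smaller in alveolar macrophages (0.44), CD4 T cells (0.41), NK cells (0.38), CD8 T cells (0.37) and T cells as a whole (0.18). In T cells Ifi27l2a had a log2 ratio of 1.24 while Ifit2, of the same list, stood at -0.97, and at 0.17 in the largest T cluster alone. T sub-cluster T11, with Ifit1, Ifit2 and Ifit3 among its leading genes, held 127 PBS and 44 PD-L1 cells.

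Genes of the interferon gamma response were higher as well. Their median was 1.09 [0.95 to 1.23] in neutrophils (11 of 14 members higher) and 1.01 [0.90 to 1.12] in monocytes (15 of 19), both at percentile 100. The guanylate-binding protein genes Gbp7 in neutrophils (2.18) and Gbp5 in monocytes (1.73) led, and Cxcl10, a chemokine that attracts T cells, stood at 1.31 in monocytes. Cd274, which encodes the checkpoint ligand PD-L1, was at 1463.7 [1432.0 to 1496.0] CPM in PD-L1 neutrophils and 885.1 [855.3 to 915.7] in PBS neutrophils, and at 222.9 [208.6 to 238.0] against 60.6 [55.7 to 65.9] CPM in monocytes. After each cell was thinned to 1000 UMIs, 59.4% of PD-L1 and 39.3% of PBS neutrophils had a Cd274 UMI, with 40 and 47 shallower cells left out (77.8% and 54.0% unthinned). For monocytes the thinned shares were 17.4% and 6.06%, with 44 and 21 cells left out (36.3% and 19.8% unthinned). The immature T-lineage cells, used as a class that should lack Cd274, gave 7.02% and 6.59%. Cd274 was at 54.4 and 65.3 CPM in them, of which free RNA could give at most 5.68 and 3.95, so these cells are no measure of background. In monocytes free RNA could give at most 11.3 and 4.57 of the 222.9 and 60.6 CPM. Median depths were 2740.0 and 2362.0 UMIs in neutrophils, 3863.0 and 7360.0 in monocytes, and 3887.5 and 3463.5 in immature T-lineage cells.

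Genes of MHC class II antigen presentation had medians above 0 in 3 classes of mononuclear phagocytes of the PD-L1 library, each at percentile 100 and with 0 members lower. The median was 0.79 [0.64 to 0.95] in monocytes (8 of 11 members higher), 0.65 [0.42 to 0.85] in alveolar macrophages (5 of 9) and 0.52 [0.43 to 0.62] in macrophages (5 of 13). H2-Ab1, a chain of the class II molecule, stood at 1.40 in monocytes and H2-Aa at 1.31 in alveolar macrophages, while Cd74, the invariant chain, stood at 1.03 and 1.23. In neutrophils the same list had a median of -0.55, which turned to 0.16 within their largest cluster. MHC class I genes had a median of 0.63 [0.55 to 0.76] in neutrophils (9 of 17 members higher), led by H2-T23 at 1.48.

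Other genes were lower in the PD-L1 library. In monocytes Chil3 (ENSMUSG00000040809), a secreted chitinase-like protein and one of the monocyte markers, was at 289.0 [272.7 to 306.1] CPM against 3514.2 [3475.8 to 3552.9], a log2 ratio of -3.56. Lcn2 (ENSMUSG00000026822), a protein that binds bacterial siderophores, was at -3.13, and Fn1 (ENSMUSG00000026193), fibronectin, was at -2.83 with 154.1 against 1156.0 CPM. Within monocyte clusters 5, 14 and 25 of resolution 2, Chil3 stood at -2.81, -2.27 and -3.13, Fn1 at -2.41, -1.84 and -1.44 and Lcn2 at -2.57, -2.51 and -0.60. In the unnamed cluster 29 they stood at -0.33 [-1.27 to 0.91], -1.45 [-2.50 to -0.40] and 0.69 [0.00 to 1.51]. In neutrophils the glycolysis list had a median of -0.71 [-0.77 to -0.63] with 12 of 16 members lower, led by Ldha, lactate dehydrogenase, at -1.15. The hypoxia list had a median of -0.90 with 7 of 11 lower, and -0.12 within the largest neutrophil cluster. The heat shock gene Hspa1b stood at -1.70 in neutrophils (-0.65 in their largest cluster) and its near-identical copy Hspa1a at -1.71, with the same uncertainty. The chemokine gene Ccl3 stood at -1.84 in neutrophils, and at -0.40 in their largest cluster. Ccl3 is also among the genes that lead neutrophil cluster 9, which held 11.9% of PD-L1 and 36.5% of PBS neutrophils. Relative to all genes, these neutrophil values are 0.16 less negative, since the median gene stood at -0.16.

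Genes of alternatively activated macrophages had a median of -0.71 [-0.81 to -0.65] in macrophages, at percentile 0, with 12 of 20 members lower. Arg1, arginase, was at 127.2 [117.9 to 137.1] CPM in PD-L1 and 899.5 [879.8 to 919.5] in PBS, a log2 ratio of -2.73. Mrc1, the mannose receptor, was at 240.0 [227.1 to 253.5] against 654.9 [638.1 to 672.0] CPM, and Pf4, a chemokine, stood at -1.99. Retnla went the other way, at 2.77. At resolution 2 the macrophages lay in cluster 20 (macrophage-like, 229 PBS, 151 PD-L1 and 136 AI-Exo cells), in the unnamed clusters 21, led by Arg1 and Mmp12 (219, 101 and 161), and 30, led by Retnla and Arg1 (115, 125 and 50), and in the neutrophil-like cluster 26 (27, 24 and 50). Within clusters 20, 21, 26 and 30 the list median was -0.92, -0.30, -0.09 and -0.71, Arg1 stood at -2.81, -1.98, -3.62 and -3.91, Mrc1 at -1.60, -0.37, -0.65 and -0.61, and Pf4 at -1.37, -2.28, -1.37 and -3.52. Retnla was at 291.5 against 1.18 CPM in cluster 20 and 558.7 against 1.70 in cluster 30, but at 14.9 against 148.3 in cluster 21 (-2.67). Pf4 is also a platelet marker, and platelet markers in free RNA were at 372.7 UMIs per 1000000 in PBS and 79.8 in PD-L1. Free RNA could give at most 33.2 and 6.90 of the 2206.2 and 549.5 CPM of Pf4 in macrophages. Macrophages made up 4.53% and monocytes 10.1% of the PD-L1 cells, and 6.93% and 14.4% of the PBS cells. Arg1 and Pf4 lead the macrophage cluster and Chil3 is a monocyte marker, so no direction is read from these shares. cDC2-like cells were at 2.15% against 3.41%, a ratio of 0.631 [0.523 to 0.759], and endothelial-like cells at 0.913% against 0.27%, a ratio of 3.38 [2.11 to 5.64].

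T cell-like cells made up 16.2% of the PD-L1 and 19.8% of the PBS cells, a ratio of 0.818 [0.762 to 0.878]. In CD8 T-like cells, genes of T cell checkpoints and exhaustion had a median of 0.69 [0.59 to 0.78], with 8 of 14 members higher and 0 lower. Rgs16, a regulator of G protein signalling, led at 1.46, and Tox, a transcription factor of exhausted T cells, was at 506.3 [478.6 to 535.3] against 286.8 [266.6 to 308.1] CPM. Pdcd1, the receptor for PD-L1, was at 104.7 [92.3 to 118.3] against 52.8 [44.3 to 62.3] CPM and Lag3 at 51.7 [43.1 to 61.6] against 20.3 [15.2 to 26.5]. The cytotoxic effector list stood at 0.25 [0.12 to 0.36] with 4 of 15 members higher, led by Ccl3 at 1.59. The CD8 class leaves out sub-cluster T10, with CD8 markers and with Ifng, Gzma and Gzmb among its leading genes. T10 held 133 PBS and 56 PD-L1 cells, against 540 and 495 in the class, and its effect on these values was not tested. The list of naive and memory T genes stood at -0.33 [-0.43 to -0.28], with Slamf6 lowest at -1.13. Different clusters led this class: T8 held 22.8% of PBS CD8 cells and T6 held 24.8% of PD-L1 CD8 cells. The largest cluster over the 3 libraries was T3, with 85 PBS and 101 PD-L1 cells. Within T3 Prf1, perforin, turned from 0.92 to -0.17. Tox and Pdcd1 stood at 1.84 and 1.73 there, against 0.80 and 0.87 over the class. In CD4 T-like cells the cytotoxic list had a median of -0.88 with 8 of 13 members lower and Ccl5 at -1.83. Within the largest CD4 cluster, T0, that median was -0.18, and Ifng turned from -1.20 to 0.04. T0 held 40.9% of PBS CD4 cells, and T1 held 30.3% of PD-L1 CD4 cells.

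In B cells the highest genes that met the naming rule were Ifi27l2a at 1.53 (1033.9 [1011.1 to 1056.9] against 352.4 [335.9 to 369.6] CPM), the phosphatase gene Dusp16 (ENSMUSG00000030203) at 1.12 and the interferon-inducible Ifi213 (ENSMUSG00000073491) at 1.11. The lowest were the small heat shock protein gene Hspb1 (ENSMUSG00000004951) at -1.01, the phosphatase gene Ptpn22 (ENSMUSG00000027843) at -0.89 and S100a4 (ENSMUSG00000001020) at -0.82. Cluster 1 held 55.4% of PBS B cells and cluster 2 held 47.7% of PD-L1 B cells. Over all T cells Rgs16 (ENSMUSG00000026475) stood at 1.25, Hist1h1b (ENSMUSG00000058773), a histone gene of dividing cells, at 0.96 and the chemokine receptor gene Ccr2 (ENSMUSG00000049103) at -1.05. Il18rap (ENSMUSG00000026068), a subunit of the interleukin 18 receptor, stood at -0.97. Within the largest T cluster these 4 values were -0.33, -0.19, -0.08 and -0.37. Neutrophils were at 19.3% against 15.6%, a ratio of 1.24 [1.15 to 1.33], which became 1.61 when the free RNA test used its likelihood statistic alone.

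**Figure D2:**
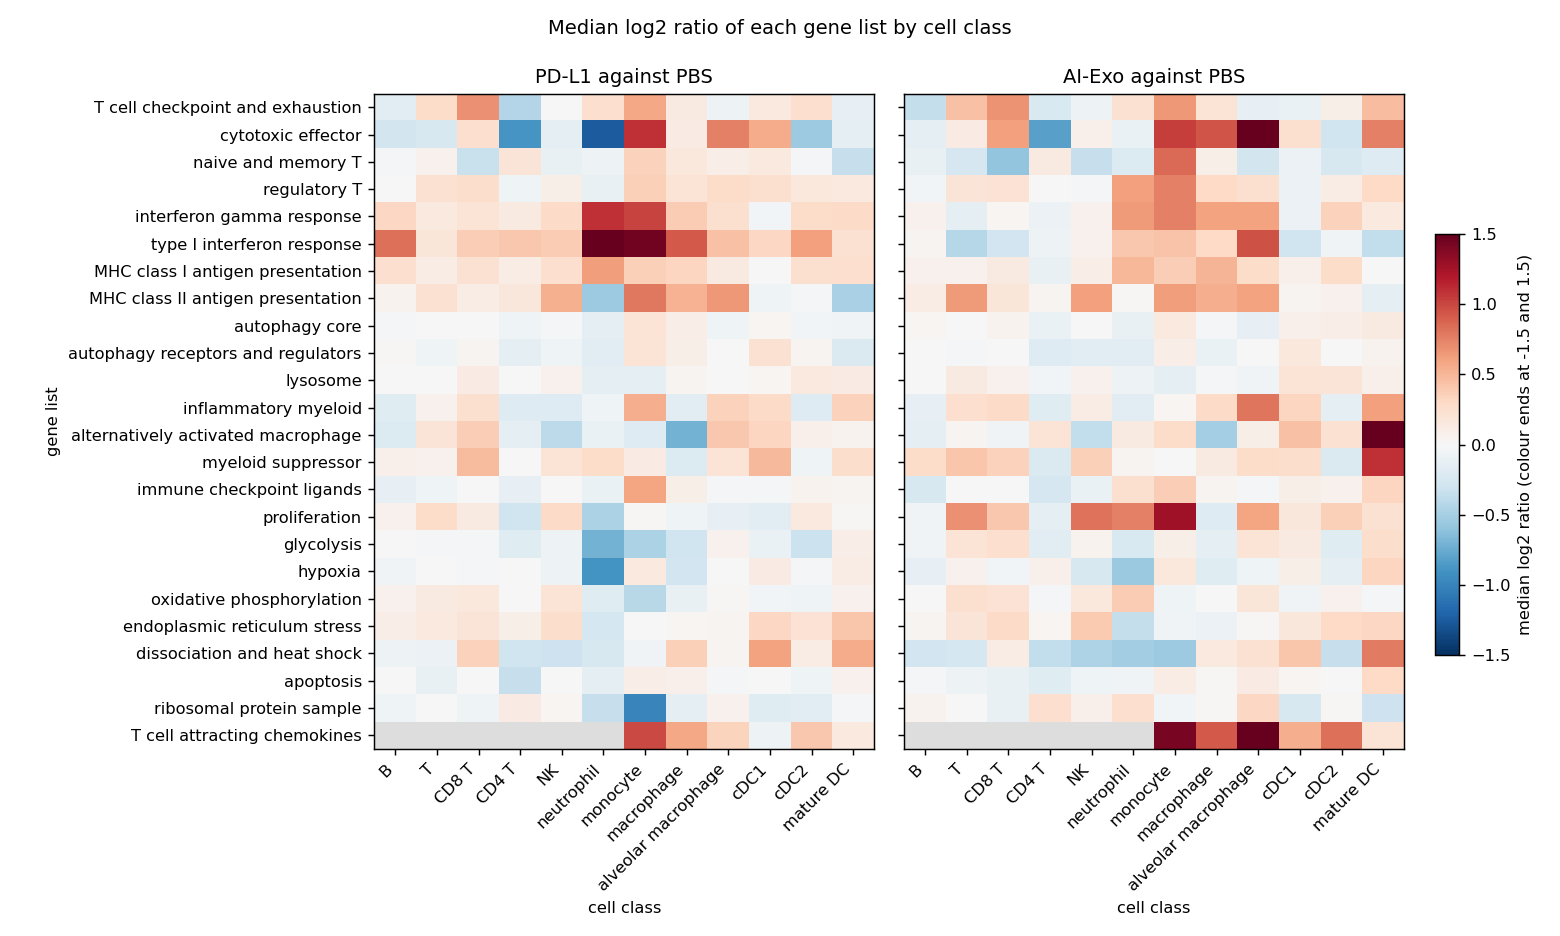
Median log2 ratio of each gene list (vertical axis) in each cell class (horizontal axis) for PD-L1 against PBS and for AI-Exo against PBS, as a colour scale that ends at -1.5 and 1.5, with grey for lists not measured. The type I interferon list stood at 2.06 in neutrophils and 1.45 in monocytes for PD-L1 against PBS, and at 0.40 and 0.43 for AI-Exo against PBS.

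The second comparison set the AI-Exo library against the PBS library. B cell-like cells made up 29.1% [28.2 to 30] of the AI-Exo cells, a ratio of 1.99 [1.86 to 2.12], and NK-like cells 6.81% against 2.67%, a ratio of 2.55 [2.19 to 2.97]. Immature T-lineage cells were nearly absent, with 4 cells against 988, a ratio of 0.00363 that became 0.0136 with 50 principal components. Chemokines that attract T cells were higher in myeloid cells, with Ccl5 (ENSMUSG00000035042) at 759.2 [733.0 to 786.2] CPM in AI-Exo monocytes and 85.7 [79.8 to 92.0] in PBS monocytes, a log2 ratio of 3.01. Within monocyte clusters 5, 14 and 25 of resolution 2 Ccl5 stood at 1.18, 2.01 and 1.34, and at 4.88 in the unnamed cluster 29. CD8 T-like cells had higher cytotoxic effector genes, with a median of 0.62 [0.55 to 0.66] and 9 of 15 members higher. That class leaves out sub-cluster T10, with CD8 markers and with Ifng, Gzma and Gzmb among its leading genes. T10 held 133 PBS and 52 AI-Exo cells, against 540 and 750 in the class. The higher median may come in part from leaving it out, which was not tested.

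With the immature T-lineage class left out of the total, the B cell ratio was 1.76 [1.64 to 1.88] and the NK ratio 2.25 [1.93 to 2.63]. The T cell ratio turned from 1.09 [1.02 to 1.16] to 0.961 [0.90 to 1.03] under the same change, and was 1.0 with cluster 17 counted among T cells. Cluster 1 held 55.4% of PBS B cells, and cluster 2 held 48.7% of AI-Exo B cells. Alveolar macrophages were at 6.68% against 4.90%, a ratio of 1.36 [1.20 to 1.55], and γδ T cells at 0.884% against 0.493%, a ratio of 1.79 [1.22 to 2.66]. cDC2-like cells were at 2.08% against 3.41%, a ratio of 0.611 [0.507 to 0.734], and endothelial-like cells at 0.495% against 0.27%, a ratio of 1.83 [1.09 to 3.16]. Neutrophils were at 15.2% against 15.6%, a ratio of 0.976 [0.905 to 1.05], and 1.30 with the likelihood statistic alone. Monocytes were at 7.22% against 14.4% and macrophages at 4.21% against 6.93%, and no direction is read from these because Chil3, Arg1 and Pf4 differed within the classes.

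The list of T cell attracting chemokines had a median of 1.73 [1.62 to 1.94] in alveolar macrophages (3 of 3 measured members higher), 1.42 [1.33 to 1.53] in monocytes (3 of 4) and 0.92 [0.89 to 1.03] in macrophages (4 of 5). With no minimum expression, members near 0 CPM entered and the medians were 0.19, 0.05 and 0.02, and with a pseudocount of 1 CPM the first and second were 2.90 and 2.13. Ccl5 led all 3 classes, at 2.49 in alveolar macrophages and 2.04 in macrophages, and Cxcl10 stood at 1.64, 1.12 and 0.92 in alveolar macrophages, monocytes and macrophages. In macrophages Cxcl9, a chemokine whose receptor Cxcr3 is found on T cells, was at 139.9 [130.7 to 149.6] CPM against 50.7 [46.1 to 55.6]. Inflammatory myeloid genes were higher in alveolar macrophages, with a median of 0.80 [0.72 to 0.97] and 11 of 15 members higher, led by Tnf at 1.65 and with Cxcl2 at 1.33.

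The type I interferon list had lower medians than in the PD-L1 library in monocytes, neutrophils, macrophages, B cells and T cells, and a higher one in alveolar macrophages (0.96 against 0.44). It had a median of 0.96 [0.85 to 1.09] in alveolar macrophages (7 of 10 members higher, Isg15 at 1.11), 0.43 [0.33 to 0.49] in monocytes (7 of 19, Ifit1 at 2.59) and 0.40 [0.36 to 0.51] in neutrophils (7 of 18, Zbp1 at 1.06). In macrophages its median was 0.30, and in B cells 0.04. In T cells it was -0.43, and 0.28 in the largest T cluster. T sub-cluster T11, with Ifit1, Ifit2 and Ifit3 among its leading genes, held 127 PBS and 64 AI-Exo cells. The interferon gamma list had medians of 0.75 [0.62 to 0.85] in monocytes (12 of 19), 0.64 [0.54 to 0.72] in neutrophils (9 of 14), 0.60 [0.53 to 0.68] in macrophages (10 of 20) and 0.60 [0.54 to 0.71] in alveolar macrophages (5 of 10). In the PD-L1 library the last 2 were 0.38 and 0.24. Cd274 was at 211.0 [197.3 to 225.5] CPM in AI-Exo monocytes against 60.6 [55.7 to 65.9], and at 1344.9 [1315.4 to 1374.9] in neutrophils against 885.1 [855.3 to 915.7]. Its log2 ratio in neutrophils was 0.60, and 1.30 within their largest cluster. MHC class II genes had medians of 0.63 [0.56 to 0.83] in monocytes (6 of 11 members higher, H2-Ab1 at 1.56), 0.60 [0.48 to 0.80] in alveolar macrophages (5 of 9, Cd74 at 1.46) and 0.54 [0.46 to 0.57] in macrophages (3 of 13), all 3 at percentile 100.

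In CD8 T-like cells Gzmb, granzyme B, was at 535.7 [512.0 to 560.2] CPM in AI-Exo and 344.1 [322.0 to 367.4] in PBS, and Ifng at 475.9 [453.6 to 499.0] against 249.7 [230.9 to 269.6]. Ccl3 led the cytotoxic list at 1.46, with Ccl5 at 0.79 and Tnf lowest at -0.55. The checkpoint and exhaustion list stood at 0.67 [0.53 to 0.74] with 8 of 14 members higher, among them Rgs16 at 1.35 and Tox at 0.68. The naive and memory list stood at -0.59 [-0.62 to -0.47] with 6 of 12 members lower, led by Il7r, the interleukin 7 receptor, at -1.29. Cluster T8 held 22.8% of PBS CD8 cells, and T3 held 34.4% of AI-Exo CD8 cells. All of these CD8 values leave out the CD8-marked sub-cluster T10. Within the largest CD8 cluster, T3 (85 PBS and 258 AI-Exo cells), Tox stood at 1.61 and Lag3 at 1.63, against 0.68 and 0.94 over the class. In CD4 T-like cells the cytotoxic list had a median of -0.81 with 9 of 13 members lower, and Ifng stood at -1.70, or -0.78 within the largest CD4 cluster, T0. T0 held 40.9% of PBS CD4 cells, and T1 held 28.8% of AI-Exo CD4 cells.

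Proliferation genes were higher in monocytes (median 1.27, 14 of 16 members higher), NK cells (0.81 [0.64 to 1.08], 15 of 23), neutrophils (0.75, 8 of 11), T cells (0.68 [0.66 to 0.79], 18 of 24) and alveolar macrophages (0.59, 13 of 25). Within the largest cluster of the class the medians were 0.21 in NK cells, 0.03 in neutrophils, 0.02 in T cells and 0.10 in alveolar macrophages, and with every cell weighed the same the monocyte median was 0.65. With a pseudocount of 1 CPM it was 2.05, and within monocyte clusters 5, 14 and 25 of resolution 2 it was 1.15, 0.44 and -0.02, and 0.76 in the unnamed cluster 29. Mki67 in alveolar macrophages turned from 0.94 over the class to -0.07 in its largest cluster, and cluster 22, with Mki67 among its leading genes, held 18.1% of AI-Exo and 6.22% of PBS alveolar macrophages. Mki67, a gene of dividing cells, was at 99.8 [89.9 to 110.6] CPM in AI-Exo NK cells and 32.3 [21.8 to 46.1] in PBS NK cells, a log2 ratio of 1.38 over the class and 0.31 in its largest cluster. After thinning to 1000 UMIs, 6.41% of AI-Exo and 1.80% of PBS NK cells had an Mki67 UMI, with 7 and 6 cells left out (14.2% and 4.82% unthinned). Neutrophils, set as the class to compare with, gave 0.714% and 0.703% but had 26.9 and 12 CPM of Mki67 and include the immature cluster 20, so they are not shown to lack it. B cells gave 0.293% and 0.407% at median depths of 3809.0 and 3208.5 UMIs. The neutrophils had median depths of 2763.5 and 2362.0 UMIs against 4910.0 and 3534.0 in NK cells. NK cluster 29 held 11.4% of AI-Exo and 2.63% of PBS NK cells, and T cluster 18, led by Gzmk, Birc5 and Hist1h1b, held 8.94% and 2.07% of the T cells. Taking the largest cluster alone leaves out these clusters and cluster 22, so its lower values for genes of dividing cells are in part by construction. Over all T cells Hist1h1b stood at 1.82 and Birc5 (ENSMUSG00000017716) at 1.33, and at -0.20 and 0.18 in the largest T cluster.

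Heat shock genes were among the lowest in several classes of the AI-Exo library. Hspa1b (ENSMUSG00000090877), an inducible chaperone, was at 201.2 [187.8 to 215.3] CPM against 1020.2 [999.6 to 1041.2] in monocytes (-2.29), 212.4 [204.3 to 220.8] against 584.1 [562.8 to 606.1] in B cells (-1.42) and 251.8 [242.7 to 261.2] against 656.5 [638.7 to 674.8] in T cells (-1.35). In neutrophils it stood at -1.34, and at -0.51 in their largest cluster. Hspa1a (ENSMUSG00000091971) stood at -1.04 in T cells and -0.44 in their largest cluster, and Hspb1 at -1.43 in B cells. The small GTPase gene Rab21 (ENSMUSG00000020132) was at 105.5 [99.8 to 111.5] against 263.8 [249.5 to 278.7] CPM in B cells (-1.25) and stood at -1.06 in T cells. The highest genes in B cells were S100a9 (ENSMUSG00000056071) at 1.83, which was 1.09 after free RNA was subtracted and 1.17 in the largest cluster, and the kinase genes Lrrk2 (ENSMUSG00000036273) and Plk2 (ENSMUSG00000021701), both at 0.66. S100a9 is one of the neutrophil markers, and free RNA could give up to 2.57% of the UMIs of AI-Exo B cells and 1.48% in PBS. In T cells Cd74 (ENSMUSG00000024610) stood at 1.41, at 2.22 after free RNA was subtracted and at 0.54 in the largest cluster. It was at 147.1 against 49.1 CPM before subtraction. Subtraction leaves less of a low value, so the larger ratio is not read as a stronger difference.

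In AI-Exo monocytes Fn1 stood at -2.46, with 201.9 [188.5 to 216.0] against 1156.0 [1134.0 to 1178.3] CPM, and Chil3 at -2.45, with 636.2 [612.2 to 660.9] against 3514.2 [3475.8 to 3552.9]. At resolution 2 cluster 14 held 788 PBS and 56 AI-Exo monocytes, cluster 5 held 221 and 295, cluster 25 held 152 and 139 and the unnamed cluster 29 held 39 and 174. Within clusters 5, 14, 25 and 29 Fn1 stood at -1.92, -1.20, -1.88 and -2.69, and Chil3 at -1.17, -1.74, -2.86 and 1.14. Ctsg (ENSMUSG00000040314), cathepsin G, stood at 2.77 but at 0.63 with every cell weighed the same, 1.85 in the largest cluster and 3.46 with a pseudocount of 1 CPM. It leads monocyte cluster 12, which held 48.1% of AI-Exo and 16% of PBS monocytes. Within resolution 2 it stood at 2.45 in cluster 5, -0.21 [-0.96 to 0.37] in cluster 14 and -0.37 [-0.79 to 0.00] in cluster 25, and was at 852.9 CPM in AI-Exo and 0 in PBS cells of cluster 29, which it leads. In neutrophils Prtn3 (ENSMUSG00000057729), proteinase 3, stood at 2.66, Ngp (ENSMUSG00000032484) at 1.93 and Camp (ENSMUSG00000038357) at 1.67, all genes of immature neutrophil granules. Within the largest neutrophil cluster they stood at 0.25, -0.26 and 0.90, and Prtn3 stood at 0.95 with every cell weighed the same and 3.41 with a pseudocount of 1 CPM. Ngp and Camp lead neutrophil cluster 20, which held 10.0% of AI-Exo and 2.56% of PBS neutrophils. The lowest were P4ha1 (ENSMUSG00000019916), a collagen hydroxylase, at -1.61 and the chemokine gene Cxcl3 (ENSMUSG00000029379) at -1.56, and at -0.85 and 0.28 in the largest cluster. In macrophages the alternatively activated list had a median of -0.51 [-0.64 to -0.45] with 9 of 20 members lower, Pf4 at -2.09 and Mrc1 at 155.3 [145.6 to 165.5] against 654.9 [638.1 to 672.0] CPM. Within clusters 20, 21, 26 and 30 of resolution 2 that median was -1.23, -0.39, 0.00 and -0.67, Pf4 stood at -1.92, -2.30, -0.20 and -2.67 and Mrc1 at -2.27, -0.71, -1.10 and -2.40. Platelet markers in free RNA were at 154.9 UMIs per 1000000 in AI-Exo and 372.7 in PBS.

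**Figure D3:**
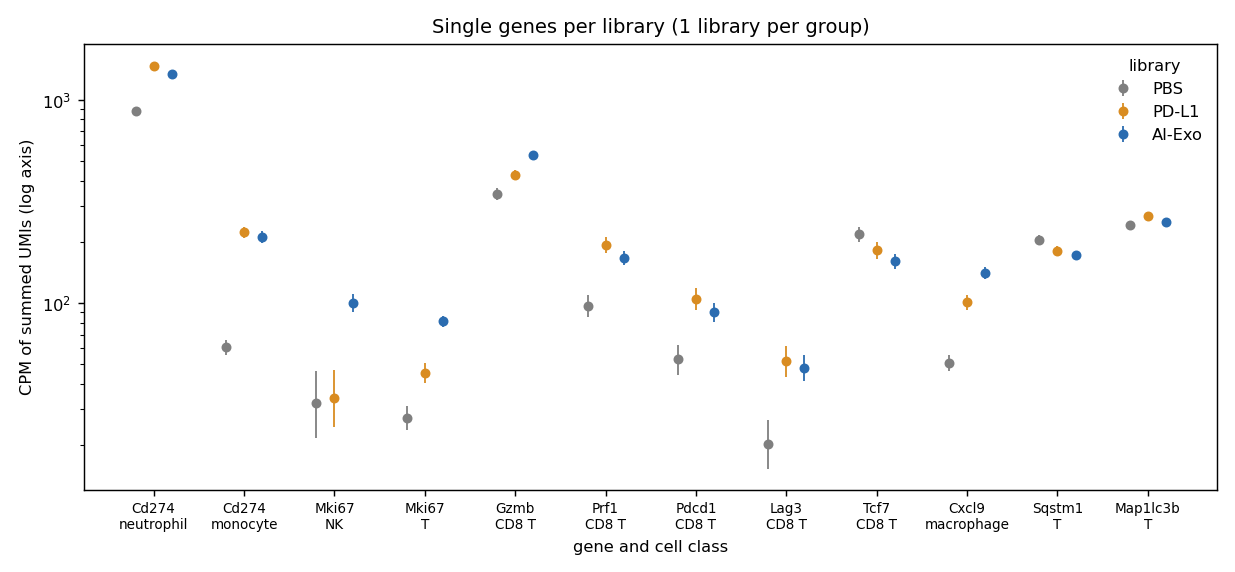
CPM (logarithmic vertical axis) of 12 gene and cell class pairs in the PBS, PD-L1 and AI-Exo libraries, with points for the value of each library and error bars for the exact 95% Poisson interval. Cd274 was at 885.1, 1463.7 and 1344.9 CPM in neutrophils and at 60.6, 222.9 and 211.0 in monocytes.

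The third comparison set the AI-Exo library against the PD-L1 library. Type I interferon genes were lower in AI-Exo neutrophils, where 18 of 18 members were lower with a median of -1.75 [-1.82 to -1.64]. They were lower in monocytes (-1.09 [-1.18 to -0.98], 16 of 19) and B cells (-0.92 [-1.01 to -0.81], 12 of 16) as well, all 3 at percentile 0. Alveolar macrophages went the other way, with a median of 0.52 [0.37 to 0.58]. In neutrophils the median of the list was -1.48 within their largest cluster. Cluster 16 of resolution 2 has interferon-induced genes among its top genes and held many of the PD-L1 neutrophils. Values within single clusters of that resolution were not taken for this list in the third comparison. NK-like cells were at 6.81% against 2.79%, a ratio of 2.44 [2.10 to 2.83], and B cell-like cells at 29.1% against 21%, a ratio of 1.39 [1.31 to 1.47].

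Ifit3 was at 80.9 [73.8 to 88.5] CPM in AI-Exo neutrophils against 669.2 [647.8 to 691.1], a log2 ratio of -2.90, with Ifit3b at -2.53 and Ifit1 at -2.34. In monocytes Slfn4 stood at -2.94 and Ifi213 at -1.89, and in B cells Ifi27l2a stood at -1.46. The list had medians of -0.64 [-0.77 to -0.52] in CD8 T cells, -0.61 [-0.72 to -0.55] in T cells and -0.60 [-0.66 to -0.54] in macrophages, with 8 of 16, 9 of 16 and 10 of 18 members lower. Rnf213 (ENSMUSG00000070327), an interferon-induced ubiquitin ligase, stood at -1.10 in T cells. Neutrophil values are relative to a median of 0.14 over all genes.

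Hnrnpa0 (ENSMUSG00000007836), which encodes an RNA-binding protein, was the lowest gene that met the naming rule in both B and T cells. It was at 84.6 [79.5 to 89.9] against 302.8 [290.6 to 315.4] CPM in B cells (-1.73) and 98.6 [92.9 to 104.5] against 330.1 [316.8 to 343.8] in T cells (-1.65). Rab21 stood at -1.07 in B cells, and Hspa1b at -2.16 in monocytes and -1.26 in T cells. Among the higher genes, Ccl5 in neutrophils was at 218.9 [207.1 to 231.2] against 26.3 [22.2 to 30.9] CPM (2.66), 2.0 in their largest cluster and 3.58 after free RNA was subtracted. Chil3 in neutrophils stood at 2.38, and 1.08 in their largest cluster, and Prtn3 at 2.73 and 0.32, or 1.25 with every cell weighed the same. In monocytes Ctsg stood at 3.57, Prtn3 at 2.44 and the tubulin gene Tubb5 (ENSMUSG00000001525) at 1.96, and with every cell weighed the same Ctsg and Prtn3 stood at 1.35 and 1.23. In the largest monocyte cluster Ctsg stood at 2.64, and a pseudocount of 1 CPM gave 5.32 for Ctsg in monocytes and 3.53 for Prtn3 in neutrophils. Within monocyte clusters 5 and 14 of resolution 2 Ctsg stood at 2.95 and 0.25, Prtn3 at 2.38 and 0.76 and Tubb5 at 2.10 and 1.75. In cluster 25 neither Ctsg nor Prtn3 had a UMI in either library and Tubb5 stood at 0.92. In the unnamed cluster 29 Ctsg and Prtn3, which lead it, were at 852.9 and 1008.8 CPM in AI-Exo and 0 in PD-L1. In B cells S100a9 stood at 1.17 (0.33 in the largest cluster), Lrrk2 at 0.41 and Top2b (ENSMUSG00000017485), a DNA topoisomerase, at 0.35. In T cells Lyz2 (ENSMUSG00000069516), a lysozyme of myeloid cells, stood at 1.14, or 0.37 in the largest cluster, 0.36 with every cell weighed the same and 2.71 after free RNA was subtracted. Cd74 and Hist1h1b in T cells stood at 1.08 and 0.87, and at 0.36 and -0.01 in the largest cluster.

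In macrophages Arg1 was at 557.3 [538.7 to 576.3] CPM in AI-Exo and 127.2 [117.9 to 137.1] in PD-L1, a log2 ratio of 2.05, and Retnla stood at -2.98. The myeloid suppressor list, which contains Arg1, had a median of 0.55 [0.49 to 0.67] with 8 of 17 members higher. Within the macrophage-like cluster 20 of resolution 2 Arg1 stood at -0.61 [-0.98 to -0.21] and that median at -0.03 [-0.10 to 0.12]. In clusters 21, 26 and 30 Arg1 stood at 1.55, 2.22 and 1.91 and the median at 0.54, -0.06 and 0.16. Retnla stood at -1.55 in cluster 20 and -1.19 in cluster 21, and was at 0 CPM in AI-Exo against 558.7 in cluster 30. Proliferation genes had medians of 1.36 in monocytes (15 of 16 members higher), 1.27 in neutrophils (9 of 11), 0.77 in alveolar macrophages (17 of 25) and 0.53 in NK cells (10 of 23). The neutrophil, NK and alveolar macrophage medians were 0.03, -0.04 and 0.26 in the largest cluster of the class, and the neutrophil and monocyte medians 0.48 and 0.65 with every cell weighed the same. The largest cluster leaves out NK cluster 29 and alveolar macrophage cluster 22 of the main clustering, so its lower values there are in part by construction. The monocyte median was 2.10 with a pseudocount of 1 CPM, and 1.48, 0.46, 0.06 and 1.70 within clusters 5, 14, 25 and 29 of resolution 2. In CD8 T cells the checkpoint list stood at -0.12 [-0.19 to -0.03], the cytotoxic list at 0.06 [-0.05 to 0.10] and the naive and memory list at -0.20 [-0.28 to -0.12], with Gzmk at 0.87 and Cxcr6 at -0.55. T6 held 24.8% of PD-L1 CD8 cells, and T3 held 34.4% of AI-Exo CD8 cells. The CD8-marked sub-cluster T10, with 56 PD-L1 and 52 AI-Exo cells, is left out of the class. Other ratios of shares were 1.33 [1.24 to 1.42] for T cells, 0.789 [0.735 to 0.846] for neutrophils, 0.968 [0.790 to 1.19] for cDC2-like cells and 0.542 [0.370 to 0.786] for endothelial-like cells.

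The title of the series names autophagy, and the core autophagy list had medians near 0 in every class measured. Its medians lay between -0.14 and 0.21 for PD-L1 against PBS, between -0.12 and 0.15 for AI-Exo against PBS, and between -0.09 and 0.17 for AI-Exo against PD-L1. In T cells the medians were 0.00 [-0.05 to 0.05], -0.01 [-0.05 to 0.04] and -0.02 [-0.06 to 0.03], with 0 of 31 members past 1.5-fold in any of the 3. Map1lc3b, which encodes the autophagosome protein LC3B, was at 240.9, 268.6 and 251.6 CPM in PBS, PD-L1 and AI-Exo T cells, and Becn1 at 54.5, 57.5 and 60.7. Atg5 was at 51.8, 48.3 and 44.9 CPM, Atg7 at 30.9, 27.8 and 27.4, and Ulk1 at 14.9, 18.7 and 18.6. Sqstm1, which encodes the autophagy receptor p62, was at 599.0 [583.2 to 615.1], 580.6 [557.3 to 604.6] and 425.9 [406.3 to 446.2] CPM in monocytes, and at 572.5 [548.6 to 597.2], 376.4 [360.4 to 393.0] and 397.8 [381.8 to 414.3] in neutrophils. The list of autophagy receptors and regulators had medians of -0.07, -0.02 and -0.01 in T cells, and the lysosome list -0.01, 0.13 and 0.08. Transcript counts do not measure autophagic flux.

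**Figure D4:**
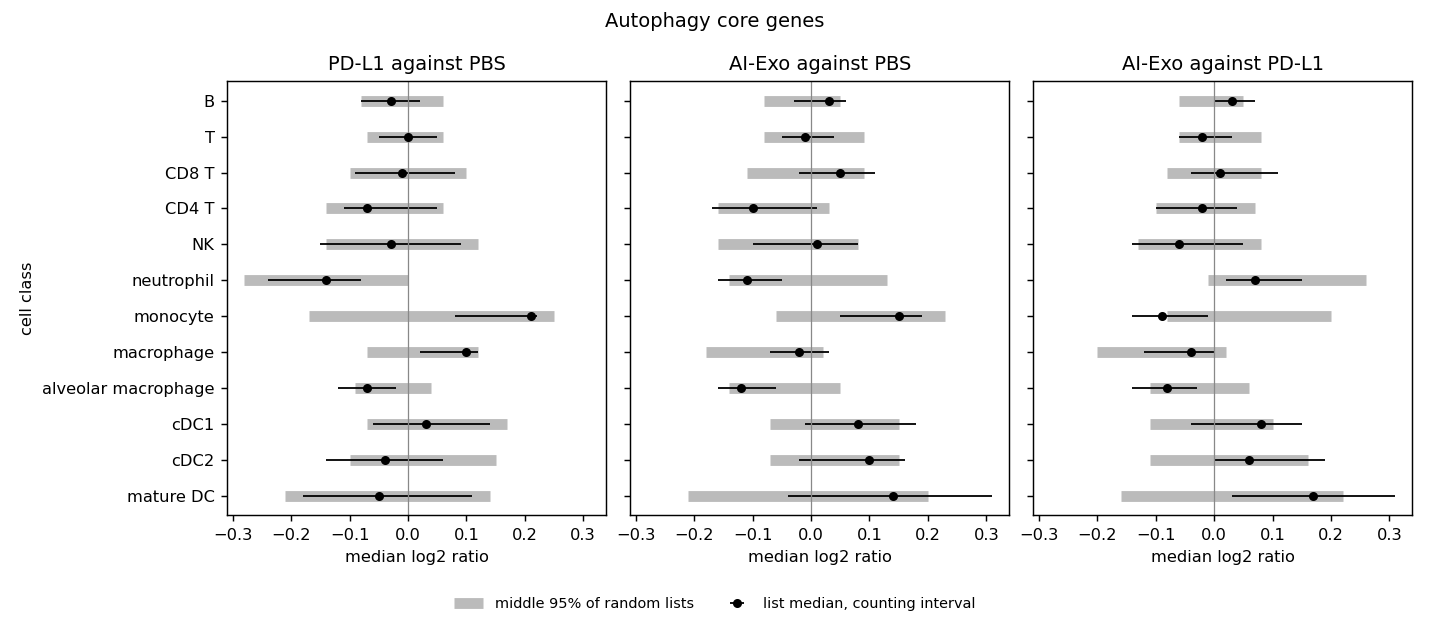
Median log2 ratio of the core autophagy list (horizontal axis) in 12 cell classes (vertical axis) for the 3 comparisons, with points for the median, error bars for its 95% counting interval and grey bars for the middle 95% of random matched lists. The T cell medians were 0.00 for PD-L1 against PBS, -0.01 for AI-Exo against PBS and -0.02 for AI-Exo against PD-L1.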

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

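The tests on Rag1, on free RNA, on scaling and on handling, and the thymus ratios without Ccl25, were chosen after the results they bear on had been seen.

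In the PD-L1 library against PBS, the cytotoxic effector list had a median log2 ratio of 1.09 in monocytes and -1.25 in neutrophils, opposite directions that lie 2.34 apart. That list also holds Tnf and chemokine genes such as Ccl3, at -1.84 in these neutrophils, so its median is not that of granzymes and perforin alone. The T cell attracting chemokines had a median of 0.99 in monocytes and -0.74 in immature T-lineage cells, 1.73 apart, and with no minimum CPM the monocyte value was 0.04. Neither difference was tested. Free RNA, which the comparisons between cells do not use, held more airway epithelial marker UMIs in AI-Exo than in PBS (542.9 against 218.5 UMIs per 1000000 free RNA UMIs, a ratio of 2.48 [2.28 to 2.70], with PD-L1 at 31.9). Fibroblast markers there had a ratio of 3.22 [2.56 to 4.09] (89.2 against 27.7, PD-L1 at 39.2). Erythroid markers had a ratio of 1.82 [1.65 to 2.01] (313.3 against 171.9, PD-L1 at 110.0). These differences between free RNA were not tested either.

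Immature T-lineage cells were found in PBS and PD-L1 (988 and 994 cells) and hardly in AI-Exo (4 cells). If thymus tissue that kept its epithelium had been loaded, thymic epithelial UMIs should have been at least 3 times as frequent as in AI-Exo, and the ratios of 1.26 [1.15 to 1.38] in PBS and 1.05 [0.955 to 1.16] in PD-L1 lay below the bound of 1.5 set beforehand against it, as did PD-L1 without Ccl25 (1.06 [0.778 to 1.44]) but not PBS (2.07 [1.59 to 2.69]). Ccl25 and Prss16 gave 791 and 74 of the 883 UMIs in AI-Exo, a baseline that would hide a small share of thymus, so neither ratio decides and thymus tissue stays open, with 72, 14 and 7 UMIs in PBS, PD-L1 and AI-Exo for Tbata, 25, 9 and 9 for Aire, 20, 1 and 0 for Fezf2, 7, 1 and 2 for Psmb11 and 0, 7 and 0 for Foxn1. Loss to the filters is argued against by Rag1, whose share of the UMIs over all AI-Exo barcodes was 0.173% of that in PBS (4 against 2061 UMIs). Thymocytes without epithelium and the treatment group, which is the same as the library, stay open and untested.

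Type I interferon genes were higher in the PD-L1 library than in PBS. After free RNA was subtracted the median stayed at 0.1 or more in 12 of 13 classes, and neutrophils would have needed 318.8% and monocytes 230.4% free RNA to carry the difference, against 3.02% and 3.90% at most. With median of ratios scaling it stayed there in 13 of 13 classes. The median gene stood between -0.16 and 0.04 in these classes, so another scaling could move the list only by little. T cells and their CD8 and CD4 parts are counted separately. The free RNA values and the small shift of the median gene argue against these technical explanations as the whole cause. The treatment group stays open and untested, since it cannot be separated from the library with 1 library per group.

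Heat shock genes were lower in several classes of the AI-Exo library than in PBS. The list used here joins heat shock genes with dissociation genes such as Fos and Jun. Its median was above 0 beyond counting error in 5 of 12 classes, among them mature dendritic cells at 0.78. In 7 it was below 0, such as monocytes at -0.54. T cells and their CD8 and CD4 parts are counted separately. These medians argue against a handling step that lowered the whole list in every cell. They decide nothing about the heat shock genes alone, because the list mixes both kinds. In the T class the list stood at -0.26 but at -0.02 [-0.08 to 0.02] in its largest cluster. Different make-up of the T class may account for the T cell value of the list, but the other T clusters were not examined. A fall confined to those clusters would leave the same value here, so make-up is not settled. Hspa1a itself stayed lower in that cluster, by less than 1.5-fold, so the shares of the T clusters alone may not account for all of its difference. The make-up within that cluster was not examined, so this does not exclude make-up. Make-up, handling and the treatment group stay open.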

How the results depend on the processing

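The likelihood statistic alone, the immature T-lineage class left out, cluster 17 counted among T cells, the largest cluster alone and the single clusters of resolution 2 were chosen as alternatives after the results had been seen. No paired analysis was possible because each group has 1 library. Unless stated, the cause was not tested. Values in parentheses are those reported. A log2 ratio is called reversed when its sign changed, even where the new value lies near no change.

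Leaving the immature T-lineage class out of the total shrinks the totals of PBS and PD-L1 by construction. AI-Exo against PBS then gave 1.76 for B cells (1.99), 0.961 for T cells (1.09, reversed), 0.863 for neutrophils (0.976) and 0.444 for monocytes (0.502). AI-Exo against PD-L1 gave 1.23 (1.39), 1.18 (1.33), 0.701 (0.789) and 0.636 (0.716). With cluster 17 counted among T cells their ratio was 1.0 against PBS (1.09) and 1.16 against PD-L1 (1.33) for AI-Exo. The likelihood statistic alone gave neutrophil ratios of 1.61 for PD-L1 (1.24) and 1.30 for AI-Exo (0.976) against PBS. Leiden resolution 2 gave monocyte ratios of 0.642 for PD-L1 against PBS (0.701), 0.378 for AI-Exo against PBS (0.502) and 0.589 for AI-Exo against PD-L1 (0.716), and a macrophage ratio of 0.533 for AI-Exo against PBS (0.607).

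In the largest cluster of the class alone, log2 ratios for PD-L1 against PBS reversed in CD4 T cells for checkpoint genes (0.52 from -0.44), naive and memory genes (-0.70 from 0.19) and Ifng (0.04 from -1.20). They reversed in CD8 T cells for lysosome genes (-0.03 from 0.12) and Prf1 (-0.17 from 0.92), and CD8 checkpoint genes moved to 0.54 (0.69). They reversed in T cells for the dissociation and heat shock list (0.05 from -0.09), regulatory T genes (-0.01 from 0.23), Pdcd1 (-0.19 from 0.76), Rgs16 (-0.33 from 1.25), Hist1h1b (-0.19 from 0.96) and Ifit2 (0.17 from -0.97), and core autophagy moved to -0.08 (0.00). Reversals were also seen for the dissociation and heat shock list in immature T-lineage cells (0.17 from -0.28). The same held for MHC class II (0.16 from -0.55) and proliferation (0.03 from -0.47) in neutrophils.

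For AI-Exo against PBS the largest cluster reversed CD4 naive and memory genes (-0.28 from 0.13). In T cells it reversed type I interferon (0.28 from -0.43), regulatory T genes (-0.10 from 0.19), Ctla4 (-0.58 from 0.62), Pdcd1 (-0.33 from 0.73) and Hist1h1b (-0.20 from 1.82). It also reversed alveolar macrophage Mki67 (-0.07 from 0.94) and neutrophil ribosomal genes (-0.02 from 0.25), Ngp (-0.26 from 1.93) and Cxcl3 (0.28 from -1.56). CD8 cytotoxic genes moved to 0.44 (0.62) and NK proliferation to 0.21 (0.81). For AI-Exo against PD-L1 it reversed CD4 cytotoxic genes (-0.10 from 0.14), NK proliferation (-0.04 from 0.53) and Mki67 (-0.14 from 1.31), and alveolar macrophage Mki67 (-0.06 from 0.77). The largest cluster leaves out NK cluster 29 (74 AI-Exo and 10 PD-L1 cells) and alveolar macrophage cluster 22, which has Mki67 among its leading genes. Its proliferation and Mki67 values in these classes are thus low in part by construction, in both comparisons. T cell oxidative phosphorylation (-0.04 from 0.11), apoptosis (-0.00 from 0.15) and Hist1h1b (-0.01 from 0.87) reversed too, as did neutrophil MHC class I (0.04 from -0.20) and myeloid suppressor genes (0.01 from -0.19). Neutrophil type I interferon moved to -1.48 (-1.75).

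Within single clusters of resolution 2, type I interferon for PD-L1 against PBS was at 1.59, 0.85, 0.27 and 1.55 in neutrophil clusters 6, 7, 16 and 33 (2.06) at 1.24 and 1.56 in monocyte clusters 5 and 14 (1.45), and at 1.31 in cluster 29, which is unnamed at that resolution. In monocytes of AI-Exo against PBS, Chil3 reversed in cluster 29 (1.14 from -2.45). Proliferation in cluster 25 (-0.02 from 1.27) and Ctsg in clusters 14 (-0.21) and 25 (-0.37, from 2.77) lost their direction. Prtn3 stood at -0.66 in cluster 25 (from 1.86). Neither Ctsg nor Prtn3 had an AI-Exo UMI in cluster 25, so these values lie near the floor. For PD-L1 against PBS, Lcn2 lost its direction in monocyte cluster 29 (0.69 from -3.13), with a counting interval that reached no change. Retnla reversed in macrophage cluster 21 (-2.67 from 2.77). In macrophages, alternatively activated genes in cluster 26 for AI-Exo against PBS (0.00 from -0.51) lost their direction. For AI-Exo against PD-L1, Arg1 reversed in cluster 20 (-0.61 from 2.05). Myeloid suppressor genes lost their direction there (-0.03 from 0.55) and in cluster 26 (-0.06). Cluster 16 has interferon-induced genes among its top genes, so its cells are alike in them in part by construction, and clusters with under 20 cells of either library gave no value.

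With no minimum CPM, CD8 checkpoint genes for PD-L1 against PBS were at 0.59 (0.69), CD8 cytotoxic genes for AI-Exo against PBS at 0.50 (0.62), alveolar macrophage MHC class II for AI-Exo against PBS at 0.40 (0.60), and neutrophil type I interferon for PD-L1 against PBS at 1.93 (2.06). Neutrophil ER stress for AI-Exo against PD-L1 reversed to 0.02 (-0.16). A pseudocount of 1 CPM gave NK proliferation 1.14 (0.81) and monocyte interferon gamma 0.88 (0.75) for AI-Exo against PBS. It gave type I interferon 1.56 in monocytes (1.45) and 2.32 in neutrophils (2.06) for PD-L1 against PBS and -1.83 in neutrophils (-1.75) for AI-Exo against PD-L1. With each cell weighed the same, NK proliferation was 0.61 (0.81) against PBS and 0.40 (0.53) against PD-L1 for AI-Exo, and monocyte type I interferon 1.36 (1.45) for PD-L1. Median of ratios scaling gave neutrophil type I interferon 2.23 (2.06) for PD-L1 against PBS and -1.93 (-1.75) for AI-Exo against PD-L1.

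A minimum of 1000 UMIs per cell moved 0 of the ratios, lists and genes beyond counting error, and free RNA subtraction moved 23 of the list values and 15 of the gene values, with 374 and 192 staying within it and 0 reversed. The largest cluster alone moved 119 list values and reversed 18, with 171 staying, and moved 97 gene values and reversed 15, with 71 staying. Weighing each cell the same moved 116 list and 85 gene values, median of ratios scaling 82 and 37, and a pseudocount of 1 CPM 52 and 44, with 0 reversed. No minimum CPM moved 53 list values and reversed 1. A limit of 10% mitochondrial UMIs, keeping doublets and omitting the test against free RNA moved 0 ratios of shares, and 50 principal components moved 4.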

Other observations

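All of the values here were singled out after they had been seen. Sub-cluster T13 of the T cells had regulatory T cell markers and held 43 PBS, 44 PD-L1 and 137 AI-Exo cells (2.54%, 3.05% and 6.69% of T cells). Foxp3, the defining transcription factor of regulatory T cells, was at 162.4 [111.8 to 228.0], 154.2 [106.8 to 215.4] and 48.3 [35.0 to 65.1] CPM within it, with a UMI in 23.3%, 13.6% and 5.19% of its cells after thinning to 1000 UMIs, which left out 0, 0 and 2 cells (46.5%, 36.4% and 17.5% unthinned). In B cells, which should lack it, the thinned share was at most 0.0813% in any library, at median depths of 3208.5, 3554.5 and 3809.0 UMIs against 4079.0, 4489.5 and 4812.0 in T13. Ikzf2 was at 2046.6, 1478.2 and 989.3 CPM, Tnfrsf4 at 1136.5, 775.4 and 416.0, and Il10 at 285.3, 317.4 and 446.3. Over all T cells Foxp3 was at 7.95, 10.3 and 8.27 CPM. Because the genes that define the sub-cluster differed between the libraries, no direction for regulatory T cells is read from its size.

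In NK-like cells Gzmb was at 988.8, 1650.6 and 1530.5 CPM in PBS, PD-L1 and AI-Exo, Prf1 at 841.4, 940.3 and 1083.2, and Ifng at 1015.7, 743.0 and 1052.2. In macrophages Spp1, osteopontin, was at 1366.6, 895.5 and 1502.1 CPM and Nos2, inducible nitric oxide synthase, at 11.1, 1.11 and 23.2. Il1b was at 9838.2, 13206.3 and 10213.3 CPM in neutrophils and 742.3, 1272.5 and 927.5 in monocytes. Platelet markers in free RNA had a ratio of 0.416 [0.376 to 0.458] for AI-Exo and 0.214 [0.188 to 0.243] for PD-L1 against PBS.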
